A study of Mus musculus with 145 samples.

How the data were processed

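Dorsal skin of mice was taken after a single exposure to ultraviolet light from a tanning canopy of 8 lamps of 100 W, whose output was 96.4% UVA and 3.6% UVB per the labels' protocols. The doses were 0 (sham), 5, 10, 20 and 40 mJ/cm2, and skin was taken at 0, 6, 24, 48, 72 and 96 h. Animals were randomized to the 30 combinations of dose and time, 5 to each, which gave 150 animals. The labels number the animals individually, so each library is a separate animal, and 5 samples were removed by the submitters because an animal died or gave little RNA. The 145 libraries analysed here fill 25 groups of 5 and 5 groups of 4. The groups of 4 are 20 mJ/cm2 at 48 h and all 4 irradiated groups at 96 h. Poly(A) RNA was made into stranded libraries from 300 ng of total RNA and read as single 75-base reads on a NextSeq sequencer, at about 40 M reads per sample, per the labels' protocols.

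The authors deposited 1 table of expected counts per gene, of which 12.6% of the values are not whole numbers. The submitters' processing notes name bcl2fastq 2.20.422, fastp 0.23.0, STAR 2.7.10a, DESeq2 1.36.1 and the genome build GRCm39. The program that made the expected counts and the annotation are not given in the sources used here. Expected counts assign reads that match several genes by estimate, so values of close relatives such as the Sprr2, Stfa, Lce and Krt6 genes can borrow from each other and are less certain than those of single genes. How strand was used in counting is not given in the sources used here, so overlapping and antisense genes are uncertain too. The table holds 55416 Ensembl gene identifiers, and 52083 of them were given a symbol through the GENCODE vM21 annotation, which is on another build (GRCm38); identifiers without a symbol held 0.0906% of the counts. That annotation was used for symbols, gene spans and spliced lengths, and no coordinates are printed.

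Total counts per library ran from 0.18 to 64.6 M (M for mega) with a median of 11.1 M, and the median library had 22263 genes above 0. The 2 shallowest libraries were 10 mJ/cm2 replicate 5 at 6 h (0.18 M) and 20 mJ/cm2 replicate 5 at 0 h (0.204 M), and the next lowest held 2.69 M. Neither enters a comparison of 40 mJ/cm2 with sham directly, but both share in its estimate of spread. Library titles end in R1_001 (71 libraries, median 9.41 M) or in R1 (74 libraries, median 12.8 M), and 5 are titled as repeats. What the title endings mark is not given in the sources used here, so the ending was carried as a covariate. No 2 libraries of a group were close enough to be the same library counted more than once: the highest correlation between pairs was 0.982 and the lowest chi-square per degree of freedom 7.6 over 280 pairs. Between groups the highest correlation was 0.988, and no chi-square was taken there, so a repeat across groups was not tested.

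The expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F tests, two-sided, TMM normalization). Genes were kept by filterByExpr with the 30 groups, which left 18677, of which 18615 have a symbol. At each time all 5 dose groups were fitted together, with the title ending as covariate, and each dose was set against the sham animals of that time. Further tests were a slope over log2 dose among the 4 irradiated groups, the change of the 40 mJ/cm2 effect between times, and the change between times in sham animals. P-values were adjusted by Benjamini and Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were taken from the fold and the F value of the same fit. Levels are CPM on TMM-scaled library sizes, as mean ± SD, and log2 CPM values use a prior count of 2.

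Designs, alternatives, gene lists and the naming rule were fixed before the data were examined. The rule takes, at 40 mJ/cm2, the 12 genes with the largest rise and the 8 with the largest fall among called genes with a mean log2 CPM of at least 1 and the same sign in every fit without 1 library. For the other doses and the slope it takes 5 in each direction, and for tests over times the 10 with the smallest p. Genes without a symbol, predicted genes (Gm, Rik) and receptor segments are not named. Not every gene the rule takes is reported here. Of the 28 gene lists, members called up and down were counted over all genes and with adjustment over the list alone. Each list was tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with the correlation estimated from the data, and with fry, adjusted over 672 tests. Camera called 212 tests with the preset correlation and 2 with the estimated one, and fry called 24. The level of a list in a library is the mean log2 CPM of its members.

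The count test was tested on simulated data drawn gene by gene from the means, sizes and dispersions of the real libraries. Changed genes were taken only from those above a floor of mean counts, so the recovered shares do not cover genes with few counts. The draws hold no differences between libraries that many genes share, so the false calls do not cover such differences. For 40 mJ/cm2 at 6 h, 37% of genes changed 2-fold and 83% of genes changed 4-fold were recovered with 4 false calls among 124, and an unchanged 5 mJ/cm2 group gave 0 calls. For 48 h the shares were 51% and 95%, with 10 false calls among 156 and 1 call in the unchanged group. DESeq2 1.42.0 recovered 63% and 91% at 6 h with 27 false calls among 181, and 68% and 95% at 48 h with 26 among 189. The test of change between times recovered 76.5% of genes changed 4-fold with 13 false calls, and the test between times in sham gave 0 false calls. A failure to call a gene at these group sizes therefore does not show that it did not change by 2-fold.

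Alternatives were DESeq2 with its size factors, RLE normalization, no filter on low counts, no title covariate, each title ending alone, 1 fit of all libraries, leaving out the repeats, a covariate for the level of muscle genes at 40 mJ/cm2, and leaving out each library. Fits without the libraries under 1 M fits with 2 surrogate variables (sva 3.50.0) and fits with the log2 share of mitochondrial counts as a covariate were chosen after seeing the data. Correlations across libraries were tested with permutations, and comparisons of list levels between groups by exact permutation tests.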

Results

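RNA was measured in the dorsal skin of mice at 6 times after a single sham or ultraviolet exposure, with 5 animals per dose and time (4 in 5 of the 30 groups) and total counts of 0.18 to 64.6 M per library (M for mega). The comparisons ask how each dose changed skin gene expression at each time, whether the change grew with dose, and how it moved over time. Fold changes below are log2 values against sham animals of the same time with their SE, and n is 5 in both groups unless another n is given. Close relatives within the Sprr2, Stfa, Lce and Krt6 families share sequence, so values of single members are uncertain.

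Directly after exposure (0 h), no gene passed the test at 40 mJ/cm2. edgeR called 0 genes at an adjusted p under 0.05 and 832 at an unadjusted p under 0.05, against 52 by DESeq2. Without sham replicate 5 the edgeR count was 2. The p53 target Cdkn1a had a log2 fold change of 0.39 ± 0.31 with an edgeR adjusted p of 1. Camera with the preset correlation still called lists at 40 mJ/cm2, with 0 members called over all genes. Epidermal differentiation genes (adjusted p = 2.52e-18) and genes of stressed and hyperproliferative keratinocytes (6.72e-08) were down, and immediate early genes (1.92e-09) up. With an estimated correlation the camera adjusted p was 0.319, 0.477 and 0.463. At 20 mJ/cm2 the edgeR count was 0 as well, with 1045 at an unadjusted p under 0.05 and 32 by DESeq2.

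At 6 h after 40 mJ/cm2, genes of stressed epidermis were among those that had risen. Sprr2h, which encodes a small proline-rich precursor of the cornified envelope, rose by 5.65 ± 0.55 (edgeR adjusted p = 4.74e-06), from 0.775 ± 0.456 to 40.6 ± 13 CPM (SD). Krt6b, a keratin of wounded and hyperproliferative epidermis, rose by 5.29 ± 0.98 (adjusted p = 0.00212), from 5.15 ± 5.14 to 175 ± 60.6 CPM (SD), and its partner Krt16 by 3.97 ± 0.75. The cornified envelope genes Rptn, Sprr1b and Sprr1a rose by 4.30 ± 0.80, 4.15 ± 0.67 and 3.06 ± 0.34. Epgn, a ligand of the epidermal growth factor receptor, rose by 3.88 ± 0.53, and Dio2, the deiodinase that activates thyroid hormone, by 3.44 ± 0.37. The AP-1 subunit gene Fosl1 rose by 2.95 ± 0.67, the hyaluronan synthase Has1 by 2.78 ± 0.69, the protease inhibitor Stfa1 by 2.72 ± 0.47 and the cytokine Il6 by 2.74 ± 0.80. The calls of Il6 and Has1 were lost in 8 and 2 of the 10 fits without 1 library. Sh3gl2, an endophilin gene, fell the most firmly, with -3.10 ± 0.31 (adjusted p = 4.74e-06). Tenm4, a teneurin adhesion gene, fell from 42.8 ± 8.89 to 7.47 ± 4.25 CPM (SD), a log2 change of -2.53 ± 0.39 (adjusted p = 0.000547). The adhesion receptors Adgrl3 and Robo2 changed by -3.16 ± 0.51 and -2.65 ± 0.48, and the potassium channel Kcnj16 by -2.90 ± 0.45. The calcium exchanger Slc24a3 and the phospholipid transporter Atp10b changed by -2.63 ± 0.53 and -2.52 ± 0.46, and Tmem132c by -2.62 ± 0.43.

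Among the fixed gene lists at 6 h, 9 of 40 measured p53 targets rose and 0 fell, and 13 rose when adjusted over the list alone. They included Pmaip1 (2.64 ± 0.31) and Tnfrsf10b (2.03 ± 0.27), which promote apoptosis, Cdkn1a (1.53 ± 0.24), the cyclin-dependent kinase inhibitor, and Mdm2 (0.89 ± 0.20), the p53 ubiquitin ligase. Cdkn1a stood at 122 ± 23.2 CPM in sham and 347 ± 83.1 CPM at 40 mJ/cm2 (SD). Of 30 genes of stressed and hyperproliferative keratinocytes, 15 rose and Serpinb3b fell, and 21 rose and 1 fell when adjusted over the list alone. Camera called both lists upward, with adjusted p = 7e-10 and 1.3e-33. With an estimated correlation the adjusted p was 0.0949 for p53 targets and 0.0106 for stressed keratinocyte genes. In the cytokine and chemokine list 5 of 29 rose, among them Lif (1.28 ± 0.35), Ppbp (2.00 ± 0.49) and the interleukin-1 antagonist Il1rn (0.87 ± 0.20), and 18 rose when adjusted over the list alone (camera adjusted p = 6.62e-10, adjusted p = 0.275 with an estimated correlation). Of the epidermal differentiation list 5 of 34 rose and 2 fell, with Lce3c at 4.94 ± 0.64 and Lce1d at -2.46 ± 0.62. The metalloproteinase genes Mmp10 (5.87 ± 0.79) and Mmp12 (2.03 ± 0.47) rose, and the T cell receptor chains Cd3g (-1.27 ± 0.27) and Cd247 (-1.11 ± 0.27) fell. Ddb2, a damage recognition gene and the sole called member of the 27 nucleotide excision repair genes, fell by 0.85 ± 0.20 on the log2 scale. Heat shock gene Hsp90aa1 rose by 1.08 ± 0.26, and the immediate early genes Maff and Fosl1 rose among 22 of that list.

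In all, edgeR called 914 genes at 6 h, 400 up and 514 down, of which 233 rose and 333 fell at least 2-fold. DESeq2 called 1675. The edgeR count was 480 without 40 mJ/cm2 replicate 2 and 481 without its replicate 5, and 1320 without the libraries under 1 M, which was chosen after seeing the data. With the level of muscle genes as a covariate it was 1724, and it was 3353 with 2 surrogate variables and 1950 with the share of mitochondrial counts as a covariate, both chosen after seeing the data. Among libraries titled R1_001 alone (3 per group) 562 genes were called, and 561 of them had the same direction among the other libraries, where edgeR called 0 genes with 2 per group and 641 had an unadjusted p under 0.05.

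At 24 h after 40 mJ/cm2 stressed keratin genes were above sham. Krt6b rose by 6.87 ± 0.86 (edgeR adjusted p = 0.000344), from 1.04 ± 0.67 to 126 ± 84.3 CPM (SD), Krt16 by 5.77 ± 0.90 and Krt6a by 3.31 ± 0.49. Sprr1b rose by 5.33 ± 0.83, and the kallikrein peptidases Klk6 and Klk10, which act in desquamation and inflammation, by 5.01 ± 0.86 and 2.80 ± 0.61. Epgn rose by 3.74 ± 0.61, the carboxylesterase gene Ces2e by 3.07 ± 0.51 and Stfa1 by 2.73 ± 0.62. Tnc, the matrix glycoprotein tenascin C of healing wounds, rose by 2.76 ± 0.38 (adjusted p = 0.000525). The connexin gene Gjb2 and the sphingolipid phosphatase gene Sgpp2 rose by 2.97 ± 0.73 and 2.74 ± 0.67, and their calls were lost in 5 and 6 of the 10 fits without 1 library. Skint7, of an epidermal gene family that shapes γδ T cells, fell from 58.2 ± 21.8 to 8.78 ± 6.7 CPM (SD), a log2 change of -2.81 ± 0.53 (adjusted p = 0.00446). The calcium exchanger Slc24a3 changed by -2.15 ± 0.26 (adjusted p = 0.000244), the ATP-gated channel P2rx2 by -2.17 ± 0.35, the adaptor Dab1 by -2.33 ± 0.37 and the kinase Pik3c2g by -2.19 ± 0.34. Tgm7 and Negr1 changed by -2.66 ± 0.54 and -2.13 ± 0.46, and the chemokine Ccl27b by -2.56 ± 0.69, a call lost in 8 of 10 fits without 1 library.

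At 24 h 16 of 40 p53 targets rose and 0 fell, against 19 up and 1 down when adjusted over the list alone (camera adjusted p = 3.03e-11, adjusted p = 0.0851 with an estimated correlation). Zmat3 rose by 1.11 ± 0.15, Tnfrsf10b by 2.14 ± 0.29 and Psrc1 by 2.29 ± 0.42. Of the stressed keratinocyte genes 14 of 30 rose, and 24 when adjusted over the list alone (camera adjusted p = 3.89e-21, adjusted p = 0.103 with an estimated correlation). Of 41 cell cycle genes 8 rose, including the ribonucleotide reductase genes Rrm2 (1.81 ± 0.33) and Rrm1 (1.01 ± 0.27), Mcm4 (1.01 ± 0.22) of the replicative helicase and Top2a (1.47 ± 0.39). Adjusted over the list alone 35 rose (camera adjusted p = 4.06e-18, adjusted p = 0.406 with an estimated correlation). In replicates 1 to 5 at 40 mJ/cm2 the level of cell cycle genes was 5.35, 4.12, 5.52, 4.32 and 3.80 log2 CPM and that of hair shaft genes 1.81, -0.48, 1.83, -0.78 and -0.68, so this rise is not separated from differences between animals in their hair follicles. The pigment genes Tyrp1 (2.66 ± 0.70) and Dct (1.76 ± 0.49) rose among 15 melanocyte markers, and 10 rose when adjusted over the list alone (camera adjusted p = 0.000468, adjusted p = 0.543 with an estimated correlation). The level of melanocyte markers in replicates 1 to 5 was 3.91, 2.28, 4.24, 2.34 and 2.86 log2 CPM, highest in replicates 1 and 3, as were hair shaft genes. This rise is thus not separated from differences in hair follicles either. The T cell chains Cd3e (-1.33 ± 0.26), Cd3g (-1.27 ± 0.29) and Trdc, 3 of 17 T cell markers, fell (adjusted p = 0.437 with an estimated correlation), as did langerin, the Langerhans cell gene Cd207 (-1.40 ± 0.34). In the muscle list, a marker of the tissue under the skin, Tnnt3 fell (-0.77 ± 0.21), and 12 of 21 fell when adjusted over the list alone.

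edgeR called 545 genes at 24 h, 309 up and 236 down (191 and 113 at least 2-fold), and DESeq2 called 1274. The edgeR count ranged widely with single libraries. It was 314, 291, 271 and 338 without sham replicates 1, 2, 4 and 5, and 1000 and 318 without 40 mJ/cm2 replicates 4 and 5. With muscle gene level as a covariate it was 4678, and with choices made after seeing the data it was 4141 (2 surrogate variables) and 4574 (the share of mitochondrial counts as a covariate, with all 545 among them). That share ran from 2.91 to 11.5% in sham and from 2.1 to 9.98% at 40 mJ/cm2. Among R1_001 libraries alone 10 genes were called, all 10 with the same direction among the other libraries, where edgeR called 0 and 477 had an unadjusted p under 0.05.

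At 48 h after 40 mJ/cm2 Saa3 and several keratin and stefin genes stood far above sham. Saa3, an acute phase serum amyloid, rose by 10.54 ± 0.83 (edgeR adjusted p = 4.5e-08), from 0.287 ± 0.22 to 517 ± 390 CPM (SD). Krt6b rose by 8.27 ± 0.81 (adjusted p = 9.13e-07), from 3.07 ± 2.88 to 882 ± 421 CPM (SD), Krt16 by 6.11 ± 0.62 and Krt6a by 4.44 ± 0.29 (adjusted p = 3.23e-09). Tnc rose by 5.23 ± 0.55, from 28.8 ± 21.5 to 1330 ± 880 CPM (SD). S100a9, a subunit of calprotectin, rose by 5.58 ± 0.94 (adjusted p = 0.000599), from 1.19 ± 1.82 to 56.9 ± 45.1 CPM (SD). Sprr1b and Sprr2a2 rose by 5.95 ± 0.58 and 4.55 ± 0.62, the stefin genes BC100530 and Stfa1 by 4.92 ± 0.69 and 4.88 ± 0.53, Klk6 by 4.49 ± 0.59, and Prg4, which encodes the lubricant lubricin, by 4.37 ± 0.44. Inmt, a methyltransferase gene, changed by -2.86 ± 0.55, Skint7 by -2.51 ± 0.45, P2rx2 by -2.15 ± 0.45 and Scd3, a fatty acid desaturase of sebaceous glands, by -2.13 ± 0.35. Ccl27b, H2-M5 and Serpinb6e changed by -2.02 ± 0.48, -1.97 ± 0.47 and -1.94 ± 0.43. Mstn, the muscle growth inhibitor myostatin, fell from 153 ± 32.1 to 42.1 ± 12.8 CPM (SD), a log2 change of -1.87 ± 0.27 (adjusted p = 0.000109).

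Many neutrophil and cytokine genes rose at 48 h, and many muscle genes fell. Of 13 neutrophil markers 10 rose, including Csf3r (3.34 ± 0.43), Cxcr2 (4.87 ± 0.66) and Lcn2 (4.29 ± 0.46), and 10 rose and 1 fell when adjusted over the list alone. Of 29 cytokines and chemokines 18 rose, including Cxcl1 (3.88 ± 0.66), Ccl2 (2.21 ± 0.39), Il1b (2.97 ± 0.53) and Il33 (1.86 ± 0.27), and 19 rose and 1 fell when adjusted over the list alone. Camera gave adjusted p = 2.4e-14 for neutrophil markers and 4.27e-14 for cytokines, and for both the adjusted p was 0.103 with an estimated correlation. Of 20 monocyte and macrophage markers 9 rose, such as Itgam (1.30 ± 0.20) and Ccr2 (1.23 ± 0.25), and 12 when adjusted over the list alone (adjusted p = 0.358 with an estimated correlation). Of 25 interferon stimulated genes 8 rose, such as Oas3 (2.19 ± 0.34) and Mx1 (1.69 ± 0.34), and the chemokine Cxcl9 fell (-1.78 ± 0.41), with 12 up and 2 down when adjusted over the list alone (adjusted p = 0.437 with an estimated correlation). Of the stressed keratinocyte genes 23 of 30 rose, and 26 when adjusted over the list alone (adjusted p = 0.0106 with an estimated correlation). Cell cycle genes rose in 8 of 41 cases, including Birc5 (1.58 ± 0.42), Plk1 (1.64 ± 0.49) and Aurka (1.18 ± 0.36), and 31 rose and 1 fell when adjusted over the list alone (adjusted p = 0.511 with an estimated correlation). Hair shaft genes moved with them between libraries, with cell cycle levels of 4.71, 5.47, 5.28, 4.68 and 5.51 beside hair shaft levels of -0.70, 1.02, 0.77, -0.55 and 1.41 log2 CPM in replicates 1 to 5, and 5.00 beside 3.14 in sham replicate 2. p53 targets still stood up in 13 of 40 cases, with Ddit4l down (-1.15 ± 0.19), and 16 up and 5 down when adjusted over the list alone (adjusted p = 0.125 with an estimated correlation).

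Matrix genes moved both ways at 48 h. The protease inhibitor Timp1 (3.46 ± 0.43), Mmp19 (1.82 ± 0.19) and Mmp3 (1.16 ± 0.31) were among 9 of 19 metalloproteinase and inhibitor genes that rose, and Timp2 (-0.83 ± 0.19) was among 3 that fell. Adjusted over the list alone 11 rose and 3 fell (camera adjusted p = 9.25e-05, adjusted p = 0.254 with an estimated correlation). Col12a1 rose (1.79 ± 0.44), while the fibrillar collagens Col1a1 (-0.79 ± 0.22) and Col1a2 (-0.94 ± 0.23) and Sparc (-0.87 ± 0.24) fell. The glutathione transferase Gsta4 (3.28 ± 0.40) and heme oxygenase Hmox1 (1.28 ± 0.26) rose among Nrf2 targets, and Gsta2 (-1.63 ± 0.36) and Gstm1 (-0.97 ± 0.26) fell. Krt14, a basal keratin, rose by 1.70 ± 0.39, and Cd207 changed by -1.87 ± 0.34. Of 21 skeletal muscle genes 13 fell and 0 rose, such as the calcium store gene Casq1 (-1.34 ± 0.23) and the myosin Myh4 (-1.20 ± 0.30). Adjusted over the list alone 19 fell (camera adjusted p = 3.96e-13, adjusted p = 0.393 with an estimated correlation). This fall of muscle genes stands beside every change at 48 h named here.

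edgeR called 1443 genes at 48 h, 741 up and 702 down (520 and 346 at least 2-fold), and DESeq2 called 1897. The edgeR count was 895 without sham replicate 5, and 842 and 957 without 40 mJ/cm2 replicates 3 and 5. With muscle gene level as a covariate it was 4471, of which 855 were among the 1443, with 2 surrogate variables 3058, and in 1 fit of all libraries 913. The share of mitochondrial counts was 4.37 ± 1.07% in sham and 2.78 ± 0.694% at 40 mJ/cm2 (SD), and 890 of the 1443 were among the 1627 called with it as a covariate. Among R1 libraries alone (3 per group) 658 genes were called, 643 of them with the same direction among R1_001 libraries, where 19 were called with 2 per group.

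At 72 h after 40 mJ/cm2 the keratinocyte and neutrophil genes were still above sham, with a wide spread between animals. Tnc rose by 5.86 ± 1.00 and Stfa1 by 5.41 ± 0.91 (both edgeR adjusted p = 0.00691), the latter from 2.57 ± 2.18 to 114 ± 110 CPM (SD). Sprr2a2 rose by 5.84 ± 1.01, Klk6 by 5.47 ± 1.02, Krt6a by 4.88 ± 0.90 and Lcn2, an iron-binding protein of neutrophils and keratinocytes, by 4.67 ± 0.86. Krt6b rose by 8.57 ± 1.96 (adjusted p = 0.0287), from 9.79 ± 19.5 to 1840 ± 2040 CPM (SD). S100a9, Krt16, BC100530, Rptn and Il1b rose by 6.42 ± 1.24, 6.99 ± 1.46, 5.84 ± 1.22, 6.49 ± 1.40 and 4.60 ± 0.97. The calls of these 5 genes and Krt6b were lost in 4 to 6 of the 10 fits without 1 library. Cd207 fell from 11.8 ± 3.31 to 3.2 ± 1.62 CPM (SD), a log2 change of -1.90 ± 0.33 (adjusted p = 0.00699), and Slc24a3 changed by -2.14 ± 0.34. P2rx2 changed by -3.31 ± 0.60, H2-M2 by -2.35 ± 0.44, Scd3 by -2.10 ± 0.42 and Cd3e by -1.99 ± 0.39. The cytokine receptors Il22ra2 and Il20ra changed by -2.56 ± 0.55 and -1.94 ± 0.40, with calls lost in 5 and 4 of 10 such fits. Of 30 stressed keratinocyte genes 20 rose, and 27 when adjusted over the list alone (camera adjusted p = 1.52e-37, adjusted p = 0.0949 with an estimated correlation). Neutrophil markers rose in 10 of 13 cases, and in 11 when adjusted over the list alone (adjusted p = 0.211 with an estimated correlation). The chemokines Ccl4 (4.95 ± 1.00) and Cxcl2 (5.88 ± 1.21) were among 9 of 29 cytokines that rose, against 18 when adjusted over the list alone (adjusted p = 0.27 with an estimated correlation). Timp1 (4.44 ± 0.78), which inhibits proteases, was among 6 of 19 metalloproteinase and inhibitor genes that rose. Slc7a11 (3.90 ± 0.83), the cystine carrier, rose among Nrf2 targets.

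edgeR called 236 genes at 72 h, 195 up and 41 down (185 and 32 at least 2-fold), and DESeq2 called 480. The edgeR count was 93, 47, 44 and 63 without sham replicates 1, 2, 4 and 5, and 39, 436, 30 and 561 without 40 mJ/cm2 replicates 1, 3, 4 and 5, with 25 genes called in every fit. It was 1271 with muscle gene level as a covariate 873 in 1 fit of all libraries and 630 with the share of mitochondrial counts as a covariate. Among R1_001 libraries alone (2 per group) 11 genes were called, all 11 with the same direction among R1 libraries, where edgeR called 0 and 587 had an unadjusted p under 0.05.

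At 96 h after 40 mJ/cm2 (n = 4 against 5 sham) the genes that rose included several of cornification. Flg, the filament-binding protein filaggrin, rose by 5.18 ± 0.90 (edgeR adjusted p = 0.0282), from 13.8 ± 16.3 to 417 ± 394 CPM (SD). The suprabasal keratin Krt1 rose by 2.31 ± 0.42 (adjusted p = 0.0305), from 993 ± 171 to 4880 ± 2950 CPM (SD), and the cornification protease Casp14 by 2.75 ± 0.48. BC100530, Stfa3 and Stfa1 rose by 7.72 ± 1.25, 6.02 ± 1.08 and 5.22 ± 0.96, the ribonuclease Endou by 2.77 ± 0.44 and the protease inhibitor Serpinb12 by 2.91 ± 0.56. Cyp2g1, Tdh, the retinol carrier Rbp2 and the glutathione transferase Gsto1 rose by 4.61 ± 0.75, 3.58 ± 0.64, 3.46 ± 0.56 and 1.63 ± 0.29. Of 34 epidermal differentiation genes 4 rose, and 29 when adjusted over the list alone (camera adjusted p = 4.47e-37, adjusted p = 0.125 with an estimated correlation). Of 30 stressed keratinocyte genes 5 rose, and 23 when adjusted over the list alone (adjusted p = 0.103 with an estimated correlation). No adipocyte gene of 19 passed over all genes, and 12 rose when adjusted over the list alone (camera adjusted p = 5.15e-19, adjusted p = 0.152 with an estimated correlation). edgeR called 22 genes, all up, DESeq2 called 94, and edgeR with the mitochondrial share as a covariate 44. Each of the 12 genes named at 96 h was lost in 4 to 7 of the 9 fits without 1 library. The edgeR count was 2, 4, 2 and 1 without sham replicates 1, 3, 4 and 5, and 9, 34, 50 and 2 without 40 mJ/cm2 replicates 1, 2, 3 and 4. Among R1 libraries alone (3 per group) edgeR called 0 genes and 585 had an unadjusted p under 0.05. Only 1 library at 40 mJ/cm2 has a title ending in R1_001, so no count is given for that ending.

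**Figure D1:**
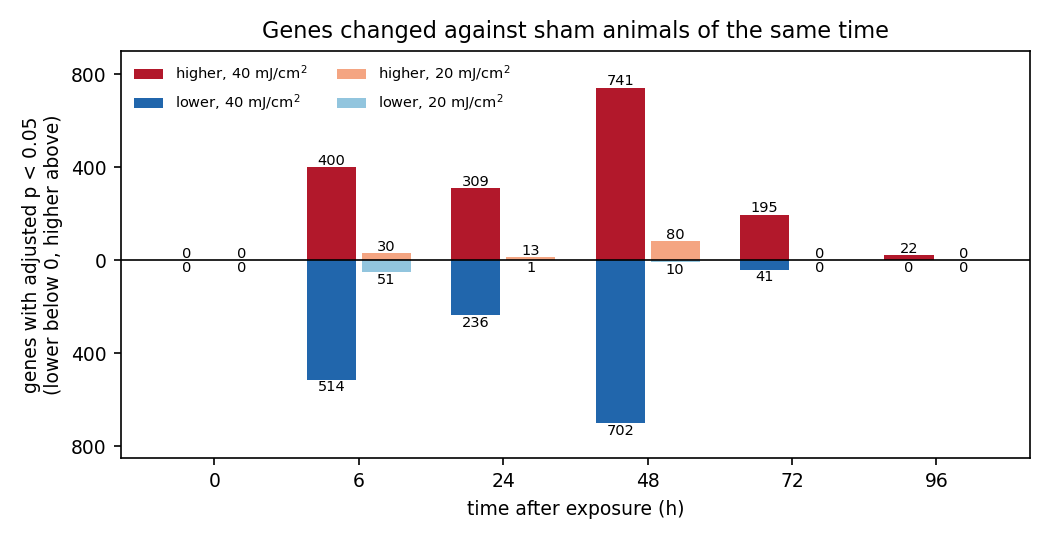
Genes called by edgeR at an adjusted p under 0.05 (y axis, number of genes, up above 0 and down below 0) against hours after exposure (x axis) at 40 and 20 mJ/cm2. At 40 mJ/cm2 the counts are 914, 545, 1443, 236 and 22 at 6 to 96 h, and 5 and 10 mJ/cm2, with 0 genes at every time, are not drawn.

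**Figure D2:**
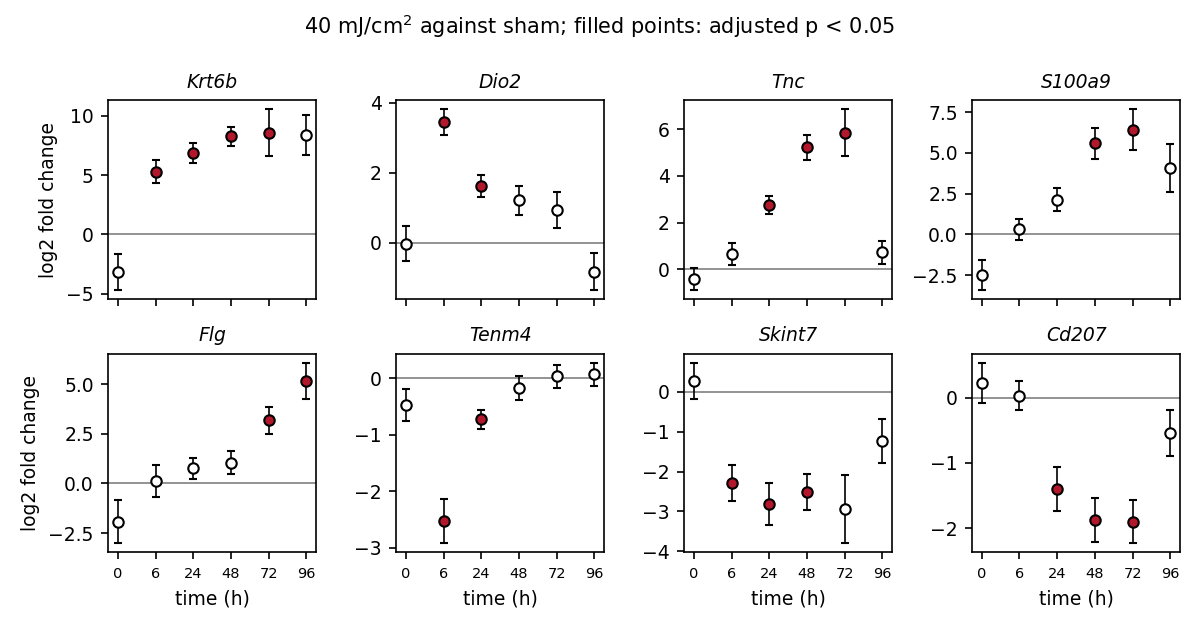
Log2 fold change of 40 mJ/cm2 against sham (y axis) at each time in hours (x axis) for Krt6b, Dio2, Tnc, S100a9, Flg, Tenm4, Skint7 and Cd207. Error bars are SE and filled points have an adjusted p under 0.05, such as Tnc with 2.76 at 24 h and 5.23 at 48 h.

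Called genes at 40 mJ/cm2 overlapped between times in the same direction, where each time has its own sham animals. Of 400 genes up at 6 h and 309 up at 24 h, 121 were shared against 6.62 for independent lists, and 80 of the falling genes were shared against 6.49. Between 24 and 48 h, 152 rising genes were shared against 12.3 and 112 falling genes against 8.87, and between 48 and 72 h 169 against 7.74 and 30 against 1.54. At all of 6, 24, 48 and 72 h the same 31 genes were called up, among them Krt6a, Krt6b, Krt16, Rptn, Sprr1a, Sprr1b, Stfa1, Lcn2 and Il6, with the water channel Aqp3, the hormone gene Fgf23 and the prostaglandin synthase Ptges. The same 12 were called down, among them Slc24a3, P2rx2, Thsd4, Col4a6, Wwox, Cd3g, H2-M2, H2-M5 and Il20ra. Part of these calls depended on single libraries, since only 25 genes in either direction were called at 72 h in every fit without 1 library. The 72 h calls of Krt6b, Krt16 and Rptn were lost in 6, 5 and 6 of 10 such fits, and the 6 h call of Il6 in 8 of 10. Genes of this paragraph beyond the naming rule were chosen after their values were seen.

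The size of the 40 mJ/cm2 change differed between times for 1012 genes in an edgeR test of dose by time. The 10 with the smallest p were Tenm4 and Itpr2 (both adjusted p = 8.21e-07), Sh3gl2 (2.48e-06), Exoc4 (2.69e-06), Jarid2 and Saa3 (both 5.08e-06), Endou (6.22e-06), Tnc (1.05e-05), Exoc6b (1.52e-05) and Serpinb12 (2.57e-05). Tenm4 and Sh3gl2 had their lowest value at 6 h, Saa3 its highest at 48 h and Endou was called at 96 h. Leaving out all libraries numbered 1, 2, 3, 4 or 5 gave 384, 338, 556, 414 and 340 genes, and DESeq2 called 1830. Among R1 libraries alone 1 gene was called. Only 1 library of 40 mJ/cm2 at 96 h has a title ending in R1_001, so no count is given for that ending.

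At 20 mJ/cm2 stressed keratinocyte genes and p53 targets rose at 6 h, in smaller numbers than 40 mJ/cm2 gave. At 6 h Sprr2h rose by 4.14 ± 0.53 (edgeR adjusted p = 0.000864), Dio2 by 2.59 ± 0.36 (0.00143) and Epgn by 2.86 ± 0.52, while Rptn and Sprr1b rose by 3.58 ± 0.79 and 3.34 ± 0.66. Thsd4 and Col4a6, a basement membrane collagen, changed by -2.49 ± 0.40 and -2.34 ± 0.37, and Slc24a3, Adgrl3 and the calcium channel Cacna1e by -2.85 ± 0.53, -2.27 ± 0.47 and -2.20 ± 0.50. At 24 h Krt6b, Krt16, Sprr1b, Klk6 and Il1f8 rose by 5.53 ± 0.82, 4.70 ± 0.85, 4.59 ± 0.81, 4.30 ± 0.84 and 2.06 ± 0.40, and the oxidoreductase Wwox changed by -0.86 ± 0.16. At 48 h (n = 4) Ces2e rose by 2.99 ± 0.34 (adjusted p = 0.000198), Stfa1 by 3.46 ± 0.52, BC100530 by 3.77 ± 0.66, Krt6b by 4.08 ± 0.70 and Saa3 by 4.33 ± 0.80. The kinase Pdk4, which restrains glucose oxidation, changed by -2.09 ± 0.43, and Negr1, Bmp3, Hpgds and Ipmk by -1.85 ± 0.39, -1.38 ± 0.28, -1.23 ± 0.27 and -0.88 ± 0.18. Of these genes, only Sprr2h, Dio2, Thsd4, Col4a6, Ces2e and Stfa1 were called in every fit without 1 library. The stressed keratinocyte list had 6, 3 and 6 of 30 genes up at 6, 24 and 48 h, and 16, 19 and 11 when adjusted over the list alone (adjusted p = 0.0851, 0.118 and 0.289 with an estimated correlation). p53 targets had 3 of 40 up at 6 h and 11 when adjusted over the list alone (camera adjusted p = 5.93e-08, adjusted p = 0.103 with an estimated correlation).

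edgeR called 81 genes at 20 mJ/cm2 at 6 h (30 up, 51 down), 14 at 24 h (13 up) and 90 at 48 h (80 up). DESeq2 called 342, 103 and 1113, and edgeR with the mitochondrial share as a covariate 358, 104 and 3. At 48 h that share was 2.74 ± 1.07% at 20 mJ/cm2 (SD, n = 4) against 4.37 ± 1.07% in sham. The edgeR counts depended on single libraries. At 6 h they were 30, 20, 27, 41 and 22 without sham replicates 1 to 5 and 32, 28 and 24 without 20 mJ/cm2 replicates 1 to 3. At 24 h they were 0, 5, 2 and 2 without sham replicates 1 to 4 and 7, 2, 29 and 2 without 20 mJ/cm2 replicates 1 to 4. At 48 h they were 7, 170, 21, 4 and 6 without sham replicates 1 to 5 and 1909, 8, 947 and 8 without 20 mJ/cm2 replicates 1 to 4. Among R1_001 libraries alone 50 genes were called at 6 h, 49 with the same direction in R1 libraries. At 72 and 96 h edgeR called 0 genes, with 206 and 790 at an unadjusted p under 0.05 and 1 and 12 by DESeq2; without sham replicate 2 at 96 h it called 2.

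At 10 and 5 mJ/cm2 no gene passed the planned edgeR test at any time, other edgeR fits called some, and some gene lists passed camera with the preset correlation. At 10 mJ/cm2 0 genes were called at each time, with 354, 1572, 825, 472, 476 and 203 at an unadjusted p under 0.05 at 0 to 96 h and 0, 33, 5, 0, 0 and 2 by DESeq2. At 5 mJ/cm2 the unadjusted counts were 635, 356, 398, 638, 642 and 1779 and those of DESeq2 0, 4, 1, 3, 0 and 4. Leaving out 1 library gave 1 gene at 10 mJ/cm2 at 6 h (10 mJ/cm2 replicate 4) and at 48 h (its replicate 3), and 2 at both doses at 96 h (sham replicate 2). At 10 mJ/cm2 and 24 h 36 of 41 cell cycle genes rose when adjusted over the list alone and 0 over all genes, with a list median of 1.07 (camera adjusted p = 3.96e-46, adjusted p = 0.103 with an estimated correlation). The levels of hair shaft genes and melanocyte markers were also above sham there, by 1.24 and 1.00 (both exact permutation p = 0.0238), beside 0.97 for cell cycle genes (exact permutation p = 0.00794), in tests chosen after seeing the data and not adjusted. At 72 h 20 and 18 of 23 hair shaft genes rose at 10 and 5 mJ/cm2 when adjusted over the list alone, with 0 over all genes and list medians of 3.79 and 3.73 (adjusted p = 0.114 and 0.198 with an estimated correlation). Of 15 melanocyte markers 9 and 10 rose in the same way, with 0 over all genes (adjusted p = 0.125 and 0.194 with an estimated correlation). Without the filter on low counts edgeR called 39, 45 and 13 genes at 10 mJ/cm2 at 0, 6 and 48 h and 56, 5, 20 and 6 at 5 mJ/cm2 at 0, 6, 48 and 96 h. In 1 fit of all libraries it called 135 at 5 mJ/cm2 at 96 h and at most 3 elsewhere at these doses. In the self-test at 6 h a 2-fold change was recovered in 37% of the changed genes, which were taken above a floor of mean counts.

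The slope over log2 dose was tested among the irradiated groups, with weight 0 on the sham group, whose libraries still enter the dispersion and the title covariate of the fit and are left out in turn as well. At 6 h Sprr2h rose by 1.80 ± 0.17 per doubling of dose (edgeR adjusted p = 1.81e-06), Dio2 by 1.18 ± 0.12 (2.14e-06), Krt6b by 1.40 ± 0.29, Rptn by 1.28 ± 0.24 and Sprr1b by 1.18 ± 0.20. Sh3gl2 had a slope of -0.82 ± 0.10 (1.92e-05), Adgrl3 of -0.95 ± 0.16, Kcnj16 of -0.80 ± 0.14, the interleukin-12 receptor gene Il12rb2 of -0.83 ± 0.15 and the metallothionein Mt4 of -0.79 ± 0.16. At 24 h the slopes of Krt6b, Krt16, Sprr1b, Klk6 and Epgn were 2.32 ± 0.27, 1.91 ± 0.28, 1.71 ± 0.26, 1.47 ± 0.26 and 1.41 ± 0.20, and those of P2rx2 and Dab1 -0.69 ± 0.11 and -0.67 ± 0.12. At 48 h Saa3 rose by 3.30 ± 0.25 per doubling (adjusted p = 1.85e-08), Krt6b by 2.91 ± 0.26, Krt16 by 2.44 ± 0.21, Sprr1b by 2.42 ± 0.20 and BC100530 by 1.96 ± 0.23. Skint7, H2-M5, P2rx2, Ccl27b and Inmt had slopes of -0.87 ± 0.14, -0.83 ± 0.15, -0.82 ± 0.14, -0.78 ± 0.15 and -0.76 ± 0.17. At 72 h S100a9, Il1b and Lcn2 rose by 1.70 ± 0.37, 1.49 ± 0.30 and 1.47 ± 0.27, and Cd207 had a slope of -0.51 ± 0.10, calls lost in 10, 6, 6 and 6 of 25 fits without 1 library. At 96 h Tdh rose by 1.37 ± 0.23, a call lost in 17 of 21 fits without 1 library.

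The slope was called by edgeR for 592 genes at 6 h (261 up, 331 down), 266 at 24 h (162, 104), 1409 at 48 h (750, 659), 77 at 72 h (70, 7) and 3 at 96 h, and for 0 at 0 h with 330 at an unadjusted p under 0.05 and 2 by DESeq2. At 6 h the count was 371 and 365 without 5 mJ/cm2 replicates 2 and 4, and 259 and 284 without 40 mJ/cm2 replicates 2 and 5. At 24 h it was 160, 170 and 171 without 5 mJ/cm2 replicates 3, 4 and 5, 434 without 10 mJ/cm2 replicate 4 and 166 without 40 mJ/cm2 replicate 5. At 48 h it was 842 and 927 without 40 mJ/cm2 replicates 3 and 5. At 72 h it was 13, 12, 7 and 21 without 5 mJ/cm2 replicates 1, 2, 4 and 5, and 10, 120, 193, 9 and 207 without 40 mJ/cm2 replicates 1 to 5. At 96 h it was 0 without any 1 of 5 mJ/cm2 replicates 1 to 4 or 10 mJ/cm2 replicate 4, 1 without 40 mJ/cm2 replicate 1 and 6 without its replicate 3. Among R1_001 libraries alone the 6 h count was 585, 546 of them with the same direction in R1 libraries, and among R1 libraries alone the 48 h count was 624, 588 of them with the same direction in R1_001 libraries.

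**Figure D3:**
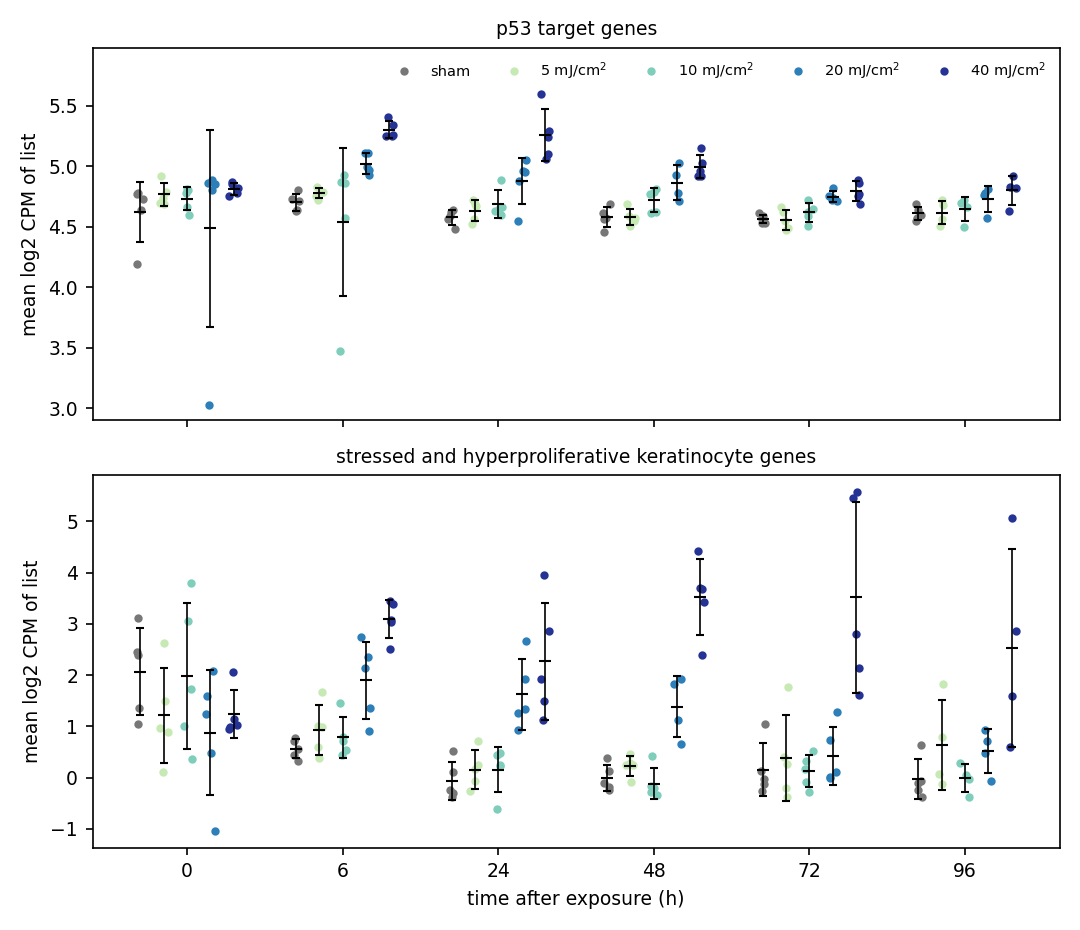
Mean log2 CPM of p53 targets and of stressed keratinocyte genes (y axis) against hours after exposure (x axis), with colours for doses; points are libraries and error bars mean ± SD. For p53 targets, the low points at 20 mJ/cm2 at 0 h and 10 mJ/cm2 at 6 h are the 2 libraries under 1 M counts. Those targets stand at 4.70 ± 0.07 in sham and 5.30 ± 0.07 at 40 mJ/cm2 at 6 h.

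In sham animals 801 genes differed between times in an edgeR test. Among those with the smallest p were the clock genes Dbp (adjusted p = 4.46e-07), Per3 (4.72e-07), Arntl (8.56e-07) and Tef (4.38e-06), the cornification genes Flg (4.72e-07), Lce1g (3.71e-06) and Krt1 (4.38e-06), the cytokine Il1f6 (9.04e-07) and Pctp (4.38e-06). Dbp stood at 5.34 ± 1.56, 49 ± 23.5, 80.6 ± 20.2, 27.8 ± 6.63, 93.5 ± 27.7 and 22.1 ± 9.25 CPM at 0, 6, 24, 48, 72 and 96 h (SD). Arntl stood at 54.6 ± 4.3, 25.2 ± 6.12, 18.1 ± 2.69, 37.7 ± 5.45, 19.2 ± 2.84 and 34.9 ± 5.95 CPM (SD). Flg and Krt1 were at 244 ± 179 and 5450 ± 2550 CPM at 0 h, against 16.7 ± 7.91 and 1810 ± 360 at 24 h (SD). Comparisons between times at a dose therefore carry this background, and each dose was set against sham of its own time. Leaving out all libraries numbered 1, 2, 3, 4 or 5 gave 364, 341, 338, 304 and 469 genes, and DESeq2 called 1832. Among R1_001 libraries alone 17 genes were called and among R1 libraries 19.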

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

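The tests of long genes in this part were chosen only after the result was seen, and the second test of spliced length only after the first had not decided.

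Single libraries stood apart from the others of their group in 13 of 89 groups of values tested, where chance gives about 4.45 for normally distributed values. Each total count and CPM value so flagged lay above the others of its group. Whether these values are normally distributed was not tested, so the excess over 4.45 is not read as faulty libraries. In total counts these were 40 mJ/cm2 replicate 2 at 6 h (22.6 M), 5 mJ/cm2 replicate 2 at 24 h (39.1 M), 20 mJ/cm2 replicate 5 at 24 h (16.7 M), 40 mJ/cm2 replicate 5 at 24 h (64.6 M) and 10 mJ/cm2 replicate 4 at 72 h (63.2 M). In Krt6b they were sham replicate 4 at 6 h (14.1 CPM), sham replicate 3 at 48 h (8.15 CPM) and sham replicate 1 at 72 h (44.6 CPM), which was also apart in Stfa1 (6.38 CPM). Sham replicate 5 at 48 h was apart in S100a9 (4.44 CPM), 40 mJ/cm2 replicate 5 at 72 h in Cd207 (6.02 CPM) and sham replicate 2 at 96 h in Flg (42.4 CPM). The level of p53 targets of 10 mJ/cm2 replicate 5 at 6 h was 3.47 log2 CPM, in a library of 0.18 M counts.

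The clock genes of 1 library did not match the time in its title, which was noticed late and not tested. In 20 mJ/cm2 replicate 5 at 0 h, titled repeat and holding 0.204 M counts, Dbp was at 87.5 CPM (17 counts) and Arntl at 5.15 CPM (1 count). The other 24 libraries at 0 h had 1.4 to 7.66 CPM of Dbp and 42.6 to 82.5 CPM of Arntl, while the Dbp value lies within the ranges at 6 h (18.3 to 89.4), 24 h (33.6 to 120) and 72 h (28.4 to 145) and the Arntl value, from 1 count, lies under the lowest at any time (10.3), in libraries over 1 M. A wrong title and other causes cannot be told apart here, and the library was kept under its label. The edgeR comparison of 20 mJ/cm2 with sham at 0 h gave 0 genes with and without it, while DESeq2 (32 genes), the fit without a filter (133) and the single fit of all libraries (66), which include it, are to be read with this in mind.

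The change at 40 mJ/cm2 differed between times, by edgeR's test of dose by time, for 1012 genes. Among them were Tenm4 and Itpr2 (both adjusted p = 8.21e-07), Sh3gl2 (2.48e-06), Exoc4 (2.69e-06), Jarid2 and Saa3 (both 5.08e-06), Endou (6.22e-06), Tnc (1.05e-05), Exoc6b (1.52e-05) and Serpinb12 (2.57e-05). Leaving out all libraries of 1 number gave 338 to 556 genes. Chance was not excluded for this count by other splits (2 of 40 had as many, highest other 1433).

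The 514 genes that fell at 6 h after 40 mJ/cm2, among them Tenm4 and Sh3gl2, had a median span of 174 kb, against 9.94 kb for the genes that rose and 18.1 kb for all genes tested. The level of 644 genes over 200 kb relative to 5661 genes under 20 kb was 0.18 ± 0.30 in sham and -0.79 ± 0.22 at 40 mJ/cm2 (SD, n = 5), a difference of -0.96 (exact permutation p = 0.00794, adjusted p = 0.0953 over 24 comparisons). The difference was -0.82 after removing its slope on the share of counts in predicted Gm genes (exact permutation p = 0.00794), so that share does not account for most of it. Whether the share measures RNA quality was not tested, so RNA quality stays undecided. As to a bias of transcript length, the span went with the change within each of 5 bins of spliced length, but 12 of 126 splits of the 10 libraries gave a weakest rho as strong as the real -0.22, so this test decided nothing; in the second test, among the genes with the longest spliced transcripts, 1007 genes spanning over 100 kb changed by -0.60 relative to 1029 spanning under 50 kb (median spliced length 7.35 and 6.2 kb, exact p = 0.00794). A candidate explanation is that lesions in DNA stop transcription more often in longer genes, which would give a fall with dose: over the 25 libraries at 6 h the relative level of long genes fell with dose with rho = -0.73 (permutation p = 5e-05, adjusted p = 3e-04 over the 6 times) and r = -0.73 (permutation p = 1e-05, the smallest these permutations can give), -0.73 without the 2 libraries farthest from the median level. Within R1_001 and R1 libraries rho was -0.86 and -0.59, but long genes were also lower at 48 h at 20 mJ/cm2 (-0.64, exact p = 0.00794, adjusted p = 0.0953), beside -0.29 at 40 mJ/cm2, late and out of dose order, and the explanation stays a hypothesis found and tested on the same libraries.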

How the results depend on the processing

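Fits with 2 surrogate variables, with the share of mitochondrial counts as a covariate and without the libraries under 1 M counts were chosen after the data were seen; the others were planned. No paired analysis was possible because the labels number animals individually and no animal or batch number is shared between groups. Over all settings, 3581 values were recomputed for 158 named results, each a gene in 1 comparison at 1 time, so that a gene can recur. Of these values 2939 kept their direction and side of the threshold, 642 kept their direction but missed the threshold, and 0 reversed. The naming rule already required the same sign in every fit without 1 library. For those fits the 0 was thus fixed in advance, and only the other settings could have shown a reversal. Of 1930 recomputed counts of list members called, for 93 counts of the lists, 1146 stayed within 1.5 times and 784 did not. Of the 212 list tests that camera called with the preset correlation, 2 tests held with an estimated correlation, and fry called 24. RLE normalization, the only other scaling run within edgeR, kept each count of called genes within 1.5 times. Depth limits the genes with few counts in sham, whose fitted folds rest on a handful of reads. The cause of the moves below was not tested, except that fits of 1 title ending or without a library hold fewer animals and the fit without a filter tests more genes.

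Counts that moved by over 1.5 times were as follows. DESeq2 called 52, 1675, 1274, 480 and 94 genes for 40 mJ/cm2 at 0, 6, 24, 72 and 96 h, 32, 342, 103, 1113, 1 and 12 for 20 mJ/cm2 at 0 to 96 h, 33, 5 and 2 for 10 mJ/cm2 at 6, 24 and 96 h, and 4, 1, 3 and 4 for 5 mJ/cm2 at 6, 24, 48 and 96 h. It called 2, 1208, 689, 272 and 46 for the dose slope at 0, 6, 24, 72 and 96 h, 1830 for dose by time and 1832 between times in sham. Without a filter on low counts there were 86, 315 and 104 for 40 mJ/cm2 at 0, 24 and 96 h, 133, 1184 and 4 for 20 mJ/cm2 at 0, 48 and 96 h, 39, 45 and 13 for 10 mJ/cm2 at 0, 6 and 48 h, 56, 5, 20 and 6 for 5 mJ/cm2 at 0, 6, 48 and 96 h, 11 and 36 for the slope at 0 and 96 h, and 603 for dose by time. Without the libraries titled repeat there were 3 and 34 for 40 mJ/cm2 at 0 and 96 h, and 2 and 9 for 20 mJ/cm2 at 24 and 48 h. With a muscle covariate there were 2, 1724, 4678, 4471 and 1271 for 40 mJ/cm2 at 0, 6, 24, 48 and 72 h. Without the libraries under 1 M there were 3 for 40 mJ/cm2 at 0 h and 138 for 20 mJ/cm2 at 6 h. Without the title covariate there were 359 for 20 mJ/cm2 at 48 h.

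With 2 surrogate variables there were 128, 3353, 4141 and 3058 for 40 mJ/cm2 at 0, 6, 24 and 48 h, 30, 1014, 168, 2909 and 1 for 20 mJ/cm2 at 0 to 72 h, 1 for 10 mJ/cm2 at 0 h, and 2800, 2223, 3144, 1346 and 1 for the slope at 6 to 96 h. With the share of mitochondrial counts as a covariate there were 1950, 4574, 630 and 44 for 40 mJ/cm2 at 6, 24, 72 and 96 h, 358, 104 and 3 for 20 mJ/cm2 at 6, 24 and 48 h, 1 each for 10 and 5 mJ/cm2 at 0 h, and 1910, 2038, 216 and 0 for the slope at 6, 24, 72 and 96 h. In 1 fit of all libraries there were 74, 913, 873 and 113 for 40 mJ/cm2 at 0, 48, 72 and 96 h, 66, 167, 287 and 1 for 20 mJ/cm2 at 0, 6, 48 and 96 h, 2, 3, 1 and 1 for 10 mJ/cm2 at 0, 6, 24 and 48 h, 2 and 135 for 5 mJ/cm2 at 0 and 96 h, and 2, 884, 452 and 58 for the slope at 0, 48, 72 and 96 h. In R1_001 libraries alone there were 562, 10, 19, 11 and 8 for 40 mJ/cm2 at 6 to 96 h, 50, 0 and 1 for 20 mJ/cm2 at 6, 24 and 48 h, 1 for 10 mJ/cm2 at 96 h, 1 and 3 for 5 mJ/cm2 at 48 and 96 h, 3, 24, 12 and 15 for the slope at 24 to 96 h, 58 for dose by time and 17 between times in sham. In R1 libraries alone there were 0, 0, 658, 0 and 0 for 40 mJ/cm2 at 6 to 96 h, 0, 0 and 9 for 20 mJ/cm2 at 6, 24 and 48 h, 0, 0, 624, 0 and 0 for the slope at 6 to 96 h, 1 for dose by time and 19 between times in sham. The counts of 0 at 40 mJ/cm2 in R1 libraries stood beside 641, 477, 587 and 585 genes at an unadjusted p under 0.05 by edgeR at 6, 24, 72 and 96 h.

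Leaving out 1 library gave 0 to 2, 480 to 955, 271 to 1000, 842 to 1682, 30 to 561 and 1 to 50 genes for 40 mJ/cm2 at 0, 6, 24, 48, 72 and 96 h. It gave 20 to 98, 0 to 29, 4 to 1909 and 0 to 2 for 20 mJ/cm2 at 6, 24, 48 and 96 h, 0 to 1, 0 to 1 and 0 to 2 for 10 mJ/cm2 at 6, 48 and 96 h, and 0 to 2 for 5 mJ/cm2 at 96 h. For the slope, with only irradiated libraries left out, it gave 259 to 852, 160 to 434, 842 to 2079, 7 to 207 and 0 to 6 at 6 to 96 h. Leaving out all libraries of 1 number gave 338 to 556 for dose by time, which was 894 without the libraries titled repeat, and 304 to 469 between times in sham. The libraries whose absence gave the lowest and highest counts at 40 mJ/cm2 were 40 mJ/cm2 replicates 2 and 4 at 6 h, sham replicate 4 and 40 mJ/cm2 replicate 4 at 24 h, 40 mJ/cm2 replicate 3 and sham replicate 2 at 48 h, 40 mJ/cm2 replicates 4 and 5 at 72 h, and sham replicate 5 and 40 mJ/cm2 replicate 3 at 96 h. The genes called in every such fit numbered 410, 199, 736, 25 and 1 at 6, 24, 48, 72 and 96 h.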

Other observations

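The tests of list levels against dose, of sham animals at 0 h against 24 h and of muscle genes were chosen only after the results were seen. The clock pattern was noticed before its tests were written. The other splits of the samples were planned, but the rule that a share under 0.05 excludes chance was written after the results were seen.

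The level of p53 targets had a positive trend with dose at each time sampled. Without the libraries under 1 M counts, rho with dose was 0.90 at 6 h, 0.78 at 24 h, 0.85 at 48 h and 0.81 at 72 h (permutation p = 5e-05 at each, the smallest these permutations can give, adjusted p = 0.0014 over 168 tests of 28 lists at 6 times). Pearson's r was 0.94, 0.88, 0.85 and 0.80 (permutation p = 5e-05 at each), and 0.91, 0.86, 0.86 and 0.72 without the 2 libraries farthest from the median level. Within R1_001 libraries rho was 0.98, 0.64, 0.86 and 0.74 at these times and within R1 libraries 0.78, 0.91, 0.86 and 0.87. At 96 h rho was 0.59 and at 0 h 0.55 (permutation p = 0.0064 and 0.0059, both adjusted p = 0.0433), with r of 0.63 and 0.40 (permutation p = 0.0026 and 0.05), 0.57 and 0.42 without the 2 farthest, and rho of 0.65 and 0.50 within R1_001 and 0.62 and 0.56 within R1 libraries. Camera did not call the list for 40 mJ/cm2 at 0 h (adjusted p = 0.194, and 0.858 with an estimated correlation). Heat shock genes had the same rho of 0.55 at 0 h, so the trend there was not particular to p53 targets. At 72 h, when edgeR called 0 genes at 20 mJ/cm2 (206 at an unadjusted p under 0.05, 1 by DESeq2), the list stood 0.18 log2 above sham (n = 5 each, exact permutation p = 0.00794, not adjusted). At 10 mJ/cm2 the difference was 0.11, 0.10, 0.11, 0.15, 0.05 and 0.03 at 0 to 96 h (exact p = 0.476, 0.214, 0.0476, 0.0476, 0.198 and 0.54, not adjusted), at 20 mJ/cm2 at 96 h it was 0.12 (exact p = 0.0952), and 5 mJ/cm2 stood level with sham at 48 h (4.58 in both) and 72 h (4.56 in both). The monocyte and macrophage list rose with dose at 6 h (rho = 0.64, permutation p = 0.0012, adjusted p = 0.0206, r = 0.71, permutation p = 2e-04, 0.57 without the 2 farthest, rho within R1_001 and R1 0.67 and 0.54). The T cell list fell with dose at 6 h (rho = -0.62, permutation p = 0.0013, adjusted p = 0.0206, r = -0.67, permutation p = 0.00045, -0.64 without the 2 farthest, rho within R1_001 and R1 -0.72 and -0.36).

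Sham replicate 3 at 0 h held 34.8% of mitochondrial counts, the highest share of all libraries, and without it the 6 lists named next still differed (exact permutation p = 0.00794, adjusted p = 0.0318), as did sterol synthesis genes. Of 28 gene lists, 6 differed in level between sham animals at 0 h and at 24 h, the clock list (4.67 ± 0.14 against 5.41 ± 0.09) and Nrf2 targets (5.35 ± 0.08 against 5.10 ± 0.13) among them, and basal keratinocyte markers did not (7.11 ± 0.58 against 7.37 ± 0.42, exact permutation p = 0.46, adjusted p = 0.635). Stressed keratinocyte genes were at 2.07 ± 0.85 against -0.06 ± 0.37 log2 CPM and epidermal differentiation genes at 6.45 ± 0.29 against 4.83 ± 0.15 (SD, n = 5 each). Sebaceous gland genes were at 7.01 ± 0.23 against 6.40 ± 0.14, and muscle genes at 9.19 ± 0.56 against 10.5 ± 0.29. For each of the 6 lists the exact permutation p was 0.00794, the smallest these splits can give, and adjusted p = 0.0371 over 28 lists. The differences within R1_001 and R1 libraries were -0.80 and -0.65 for clock genes, 0.19 and 0.34 for Nrf2 targets and, for the other 4 in the order given, 2.38 and 1.76, 1.69 and 1.52, 0.70 and 0.47, and -1.49 and -1.01. Hair shaft genes varied between animals, with 2.18 ± 2.05 at 10 mJ/cm2 and 2.06 ± 1.62 at 5 mJ/cm2 against -0.26 ± 0.72 in sham at 72 h, and melanocyte markers with 3.73 ± 1.24 and 3.66 ± 1.09 against 2.15 ± 0.51 (SD, n = 5 each).

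Clock genes differed between the sham times: 13 of 18 measured were called by edgeR, with Dbp, Per3, Arntl and Tef among the 10 smallest p. With the share of counts in predicted Gm genes as a covariate 17 of the 18 were called, so that share does not account for the differences. Whether it measures RNA quality was not tested. A candidate explanation is that animals were killed at different phases of the daily clock, in which genes of the Dbp and Arntl limbs move in opposite directions. Over the 6 group means the limbs had rho = -0.94 (exact permutation p = 0.0167) and r = -0.97 (exact permutation p = 0.00417), -0.93 without the 2 times farthest from the median. The hours of killing were not used here, so this stays a hypothesis.

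Skeletal muscle genes were lower at 48 h after 40 mJ/cm2, with log2 changes from -1.53 to -0.53 and a median of -1.14. A candidate explanation is less muscle tissue in these biopsies, which would move all muscle genes by a like amount, and 20 of 21 lay within 0.5 of the median. A change of muscle gene activity with dose cannot be told apart from it, since the fall of the list with dose over 24 libraries (rho = -0.56, permutation p = 0.00517, and r = -0.65, permutation p = 8e-04, -0.71 without the 2 farthest libraries) is what both would give. Within R1_001 and R1 libraries rho was -0.45 and -0.63. With the level of muscle genes as a covariate, 855 of the 1443 genes called at 48 h were among the 4471 then called.

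Other splits of the same libraries into groups of the same sizes were counted with the real split. Chance was excluded, at a share under 0.05 not adjusted over the 32 results so tested, as the source of the 914 genes at 40 mJ/cm2 at 6 h (as many in 1 of 100 splits, highest other 1) and 1443 at 48 h (1 of 100, 87). It was excluded in the same sense for 20 mJ/cm2 at 6 h (81 genes, 1 of 100, 1) and 24 h (14, 1 of 100, 0), for the dose slope at 6 h (592, 1 of 100, 2), 24 h (266, 1 of 100, 0) and 48 h (1409, 1 of 100, 55), and for differences between times in sham animals (801, 1 of 40, 35). The share was under 0.05 too, but another split gave nearly as many genes or more, so that chance is left open, for 40 mJ/cm2 at 72 h (236, 2 of 100, 1281) and 96 h (22, 1 of 100, 21), 20 mJ/cm2 at 48 h (90, 2 of 100, 242) and the slope at 72 h (77, 2 of 100, 88) and 96 h (3, 3 of 100, 5673). Chance was not excluded for the 545 genes at 40 mJ/cm2 at 24 h (5 of 100, 6703) or for the 1012 genes of dose by time (2 of 40, 1433). These splits move libraries without regard to replicate number, with which the mitochondrial share went at 24 h. Each real group at 24 h holds replicates 1 to 5, so free splits can part high from low shares as the real groups do not. They therefore cannot decide on chance there. Apart from the splits, the sets at 40 mJ/cm2 overlap between times with separate animals and separate sham: 152 rising and 112 falling genes were shared by 24 and 48 h (12.3 and 8.87 if independent) and 169 and 30 by 48 and 72 h (7.74 and 1.54), with 0 in opposite directions. Chance alone does not give such shared sets from independent genes. Genes that vary together between animals could raise the overlap, and it was not compared with the overlap of other splits. The shared sets therefore do not decide what the splits leave open at 24 and 72 h.

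Where edgeR called 0 genes, all of 20 splits reached that number by definition. The highest other count was 5792 for 40 mJ/cm2, 4 for 20 mJ/cm2, 7021 for 10 mJ/cm2 and 0 for 5 mJ/cm2 and the slope at 0 h. It was 7565 for 10 mJ/cm2 at 24 h, 29 for 5 mJ/cm2 at 96 h and 0 for 20 mJ/cm2 at 72 and 96 h, for 10 mJ/cm2 at 6, 48, 72 and 96 h and for 5 mJ/cm2 at 6 to 72 h. Splits with several times the real count, as at 0 h, at 24 h, at 72 h for 40 mJ/cm2 and at 96 h for the slope, point to a structure among the libraries other than dose.

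That structure was looked for only after the splits were seen. At 24 h the split of sham and 40 mJ/cm2 libraries with 6703 genes parted those with 7.12 to 11.5% of mitochondrial counts from those with 2.1 to 5.3% (exact permutation p = 0.00794, the smallest these assignments can give, not adjusted), and that with 7565 genes at 10 mJ/cm2 parted 7.12 to 16.3% from 2.38 to 4.51% (exact permutation p = 0.00794). At 0 h the splits with 5792 and 7021 genes followed the share too (exact permutation p = 0.00794 and 0.0159), while at 72 h the split with 1281 genes did not (exact permutation p = 0.619). With the share as a covariate, the real split at 24 h gave 4574 genes, as many in 1 of 100 splits, highest other 616. At 72 h the real split gave 630, as many in 2 of 100, highest other 4735. The covariate was chosen because a split that beat the real one at 24 h followed it, and the same splits were counted again. These fits therefore cannot exclude chance, which stays open at both times. What makes the share differ between animals, RNA quality, tissue or something that goes with the replicate number, was not tested.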
